A study of Homo sapiens with 8 samples.

How the data were processed

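RNA was measured on 8 one-colour Agilent arrays (Cy3 label, whole human transcriptome). PC-9 and H1975 are established EGFR-mutant lung adenocarcinoma lines. Each line was left untreated or treated for 24 h with pemetrexed, osimertinib or both, each at a dose equal to its IC50, per the labels. Pemetrexed is an antifolate that blocks thymidylate and purine synthesis. Osimertinib is an inhibitor of mutant EGFR. Each of the 8 combinations of line and treatment had 1 array, so there were no replicates within a line. The series description names an Affymetrix platform and mentions drug-resistant lines, but the files are Agilent Feature Extraction output and hold the 8 arrays described here.

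The scanner files give spot brightness as intensity, per the file headers, from Feature Extraction 11.5.1.1 for PC-9 and 12.1.1.1 for H1975. The authors' processed signal column is an intensity after subtraction of local background, with a small positive substitute for dim spots and no normalization between arrays. The authors also deposited a table of log2 values. Its PC-9 columns share 1 distribution, as after quantile normalization within the line (median 3.114 in each), whereas each H1975 column is log2 intensity minus 1 constant (median -3.291 for control, -3.557 for pemetrexed, -3.2 for osimertinib and -3.332 for the combination). Because these columns were scaled differently by line, the deposited log2 table served as an alternative only. The 4 PC-9 arrays came from 1 slide, 1 scan and 1 software version and the 4 H1975 arrays from another, so the line and these technical steps cannot be told apart. Probe positions are those of build hg19, per the file headers. The probe positions printed in the text span 60 bases each, and the files do not say whether they lie in a coding region or a UTR.

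Every array had 60901 spots. The 75th percentile of signal was 176, 191, 175 and 174 on the PC-9 arrays and 128, 142, 123 and 122 on the H1975 arrays (control, pemetrexed, osimertinib, combination). The share of spots well above background by Feature Extraction's own flag was 54.9%, 56.3%, 55.8% and 54.0% in PC-9, and 62.7%, 58.7%, 61.9% and 59.7% in H1975. No spot was saturated. Among 300 probes spotted repeatedly, the median SD of log2 signal was 0.0569 or lower on every array. The number of arrays limits the precision of all comparisons.

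The log2 processed signal of each array was reduced by its own 75th percentile over the 58201 probes that were not controls. In all, 11 probes were left out because of outlier flags. Accessions of 31104 probes matched the gene table, 3367 symbols changed to those in current use, and 1507 probes had no gene name. Probes well above background on at least 2 of the 8 arrays were kept (37407), and the probe with the highest mean stood for each gene, which left 27759 genes. A few older symbols, such as HIST1H2AC, remained where the table held no match.

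Comparisons were fitted in limma 3.58.1 (R 4.3.3) with treatment and cell line as terms, which leaves 3 residual degrees of freedom. Contrasts compared osimertinib, pemetrexed and the combination with control, the combination with each drug alone, and the departure of the combination from the sum of the single effects on the log2 scale. The lines served as the units of replication. The SE and p-value therefore measure how far PC-9 and H1975 depart from a common effect, n = 2 arrays per treatment. Differences within 1 line are single values with no test. Another fit with terms for the interaction of line with each drug tested whether the lines differed, comparing the 2 arrays with a drug to the 2 without it in each line (2 residual degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over the 27759 genes and a threshold of 0.05. After the data were seen, an additive fit was added that compares the 4 arrays with a drug to the 4 without it, with the other drug and the line as terms. That fit counts each array as a unit, 2 per line on each side, so its SE and p-value do not treat the lines as the replicates.

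The lists tested, 30 in all, covered MAPK output, EGFR family and ligands, bypass receptors and ligands, G1/S and DNA replication, G2/M, folate and thymidylate, purine and pyrimidine synthesis, p53 targets, DNA damage response and repair, BCL2 family and inhibitors of apoptosis, ATF4 amino acid response, unfolded protein response, sterol and fatty acid synthesis, interferon response, NF-kB targets and cytokines, mesenchymal, epithelial, YAP/TEAD targets, hypoxia and glycolysis, lung epithelial lineage, lysosome and autophagy, ribosome biogenesis and MYC targets, polyadenylated histone genes, CDK inhibitors and quiescence, heat shock, neuroendocrine, and markers of fibroblasts, leukocytes, endothelium and erythroid cells. The lists overlap only in ENO2 (neuroendocrine and hypoxia lists) and PDGFRB (bypass and fibroblast lists). Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 180 tests (30 lists in 6 comparisons). The same lists were tested for the difference between the lines with each drug, after the results were seen, adjusted separately over 60 tests (30 lists and 2 drugs). Camera with an estimated correlation and limma's fry stood beside it. Per line, a list's median was ranked among those of 10000 random lists of the same size and similar expression.

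The lists, the tests of the comparisons and lists, the rule for named genes and the alternatives were chosen before the data were examined. The exceptions were the additive fit, the tests of lists without each array and the tests of lists for a difference between the lines. Counts of genes adjusted over a list alone were not planned either. Such counts take no account of the number of lists or of correlation between genes. Genes named for a comparison were a fixed panel of 12, the 8 highest and 8 lowest by the smaller of both lines' differences among genes moving the same way in both, and up to 4 members along and 2 against each list. They had to be well above background on at least 1 of the compared arrays in each line. The non-additivity rule left open which arrays counted, and well above background on all 4 arrays of each line was required. For line differences the 5 genes in each direction were taken by size alone, because none passed. Placeholder and accession names were left out, and 4 genes that met these rules are not reported here. Where 1 of the compared arrays was not well above background, the size is given as "at least N-fold", computed against the higher of the gene's own signal and the lowest signal well above background on that array. For an effect over 4 arrays of a line, both arrays of the higher side had to be well above background.

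Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, centring on the median of detected probes, no filter on dim probes, a filter for signal on all 8 arrays, the mean of all detected probes of a gene, the authors' log2 table, an intensity trend in the variance prior, no cell line term, the arrays of the comparison alone, an estimated correlation, and each array left out. Normexp was planned on mean spot brightness, but the H1975 files lack that column, so median brightness was used on all arrays. Slide as a block could not be fitted beside cell line. With 1 array left out, the fit filled in its value from the line difference under the other treatments. Medians given without an array therefore draw on all treatments and can lie outside both lines' own values. The fits were tested on simulated data with 50 changed genes per size among 27759. The planned fit, for osimertinib against control, called 1, 36, 43 and 46 of 50 at log2 changes of 1, 2, 3 and 4, with 4 false calls, and the additive fit, for osimertinib present against absent, 25, 47, 49 and 50, with 7 false calls. Camera called a simulated shifted list and did not call an unshifted one. The simulated noise was independent between genes and each change was the same in both lines. These checks therefore do not cover correlated genes, for which the estimated correlation reached 0.89 (G1/S list), or effects that differ between the lines. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots in matplotlib 3.10.9.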

Results

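Expression was measured in PC-9 and H1975 cells, lung adenocarcinoma lines with activating EGFR mutations, under 4 treatments: control, pemetrexed, osimertinib and the combination. There was 1 array per line and treatment, 8 in all, and 27759 genes had signal above background on at least 2 arrays. Values are log2 signal relative to the 75th percentile of the array. A pair of log2 differences is given as PC-9 then H1975, a mean over both lines has its SE from limma, and no line had replicates. The p-values of gene lists are from camera, adjusted over all lists and the 6 comparisons of treatments. By limma's fry no list passed in any of them (smallest adjusted p 0.182, and 0.273 for non-additivity).

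The arrays with osimertinib alone were compared with control to ask what blocking EGFR did to expression. Transcripts that report signalling through the MAPK pathway were lower in both lines. DUSP6, a phosphatase that feeds back on ERK (probe on chromosome 12, 89742144 to 89742203), differed from control by -5.54 in PC-9 and -2.90 in H1975 (mean -4.22, SE 0.80). The ETS factor ETV4 (chromosome 17, 41605966 to 41606025) differed by -3.37 and -3.12 (mean -3.24, SE 0.49). SPRY4, an inhibitor of receptor signalling, was at least 16.6-fold lower in PC-9 and differed by -2.87 in H1975, although another SPRY4 probe, taken when signal on all 8 arrays was required, had a mean of 0.04. ETV5 was at least 37.2-fold lower in PC-9 and differed by -2.83 in H1975. The MAPK output list fell, with a median of -2.35 in PC-9 and -1.47 in H1975 (camera adjusted p = 3.72e-11), 18 of its 22 genes being lower in both lines and 12 at least 2-fold lower in both. Adjusted p = 0.614 with an estimated correlation.

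Genes for cell division and for making ribosomes were also lower with osimertinib. The ribosome biogenesis and MYC target list fell (medians -0.88 and -1.05), all 30 genes being lower in both lines (adjusted p = 8.54e-18). LYAR differed by -1.53 and -1.78, the polyamine enzyme ODC1 by -1.40 and -1.41, and BOP1 by -1.37 and -1.25, with MYC itself at -0.85 and -0.65. The G2/M list fell (-0.56 and -1.47, adjusted p = 1.34e-14), with all 37 genes lower in both lines, among them the mitotic kinases PLK1 (-1.13 and -1.82) and AURKA (-0.82 and -1.86). The G1/S and DNA replication list fell as well (-0.30 and -1.70, adjusted p = 4.85e-12, 33 of 37 genes lower in both), as did DNA damage response and repair (-0.31 and -1.29, adjusted p = 4.16e-07, 20 of 24). MCM10, a replication factor, differed by -0.66 and -2.32, cyclin E1 (CCNE1) by -0.94 and -0.76, and the checkpoint kinase CHEK1 by -0.85 and -0.88. With an estimated correlation, adjusted p = 0.614 for each of these 4 lists.

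Purine and pyrimidine synthesis fell (-0.48 and -0.87, adjusted p = 6.84e-08, 15 of 16 genes lower in both lines), with PFAS at -0.88 and -0.94 and PPAT, the first enzyme of purine synthesis, at -0.85 and -1.07. Heat shock genes fell (-0.42 and -0.76, adjusted p = 3.88e-05, 13 of 15), led by HSPA8 (-1.02 and -1.35). CDK inhibitors and quiescence genes rose (0.50 and 0.33, adjusted p = 0.00349, 13 of 21 higher in both), with YPEL3 at 2.33 and 1.73, the translation inhibitor PDCD4 at 1.49 and 1.44 and CCNG2 at 1.37 and 1.29. Lysosome and autophagy genes rose (0.32 and 0.35, adjusted p = 0.00356, 15 of 24), with GABARAPL1 at 2.48 and 1.94 and the autophagy kinase ULK1 at 1.30 and 1.35. Adjusted p = 0.614 with an estimated correlation for each of these 4 lists. Folate and thymidylate genes had medians of -0.29 and -0.61 (adjusted p = 0.0023, and adjusted p = 0.614 with an estimated correlation). Of the enzymes that pemetrexed inhibits, thymidylate synthase (TYMS) was at -0.39 and -1.72 and GART at -0.64 and -0.81. The folate carrier SLC19A1 was lower (-1.10 and -1.19), and the folate receptor FOLR1 was higher (2.13 and 1.496).

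Among named genes, the largest difference shared by both lines was in VTCN1, the immune checkpoint ligand B7-H4 (chromosome 1, 117686598 to 117686657). It was 120-fold higher with osimertinib in PC-9 and 23.4-fold higher in H1975 (mean 5.73, SE 0.59). COLCA1 was at least 6.80-fold and 9.19-fold higher, ECEL1P2 was higher by 4.53 and 3.23, and SELENOP, a selenium transport protein, was at least 12-fold higher in PC-9 and higher by 2.97 in H1975. ACOX2, a peroxisomal oxidase of bile acid synthesis (chromosome 3, 58490908 to 58490967), differed by -4.52 and -3.42 (mean -3.97, SE 0.30). The ectonucleotidase NT5E (CD73, chromosome 6, 86204891 to 86204950) differed by -2.95 and -3.10, the lipid transporter MFSD2A by -3.03 and -3.21, and the lipase inhibitor ANGPTL4 was at least 12.7-fold lower in PC-9 and differed by -3.06 in H1975. EGFR itself differed by -0.50 in both lines, CCND1 by -0.59 and -1.78, BCL2L11 by 1.00 and 0.43, CDKN1A by -0.60 and 0.07 and MKI67 by -0.68 and -1.44.

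In all, 559 of 22917 genes were at least 2-fold higher in both lines, where 85.3 would be if the lines were unrelated, and 206 were at least 2-fold lower in both against 40.8. Across genes, which are not independent replicates, r between the lines was 0.48. In the planned limma test 0 genes passed (smallest adjusted p 0.138), although 5331 had an unadjusted p under 0.05. Adjusted over the list alone, 30 ribosome, 31 G2/M, 16 MAPK, 11 purine, 0 G1/S and 0 DNA repair genes passed. In the additive fit, added after the data were seen and with arrays rather than lines as units, 2449 genes passed, 1114 up and 1335 down. Among them were VTCN1 (4.83, SE 0.52, adjusted p = 0.0234), ACOX2 (-4.21, SE 0.21, adjusted p = 0.0116), ETV4 (-3.26, SE 0.32, adjusted p = 0.023) and DUSP6 (-3.70, SE 0.56, adjusted p = 0.0286). MYC and GART also passed there, but EGFR, CCND1, TYMS, CDKN1A, BCL2L11 and MKI67 did not. The median over both lines of G1/S genes was -1.005, and -0.38 without the H1975 osimertinib array or -1.67 without that of PC-9. DNA repair moved from -0.74 to -0.28 and -1.19 and G2/M from -1.01 to -0.55 without H1975 osimertinib, MAPK output from -1.70 to -0.97 with normexp, and the folate list from -0.41 to -0.25 (adjusted p = 0.12) without H1975 osimertinib and to -0.65 without PC-9 osimertinib.

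**Figure D1:**
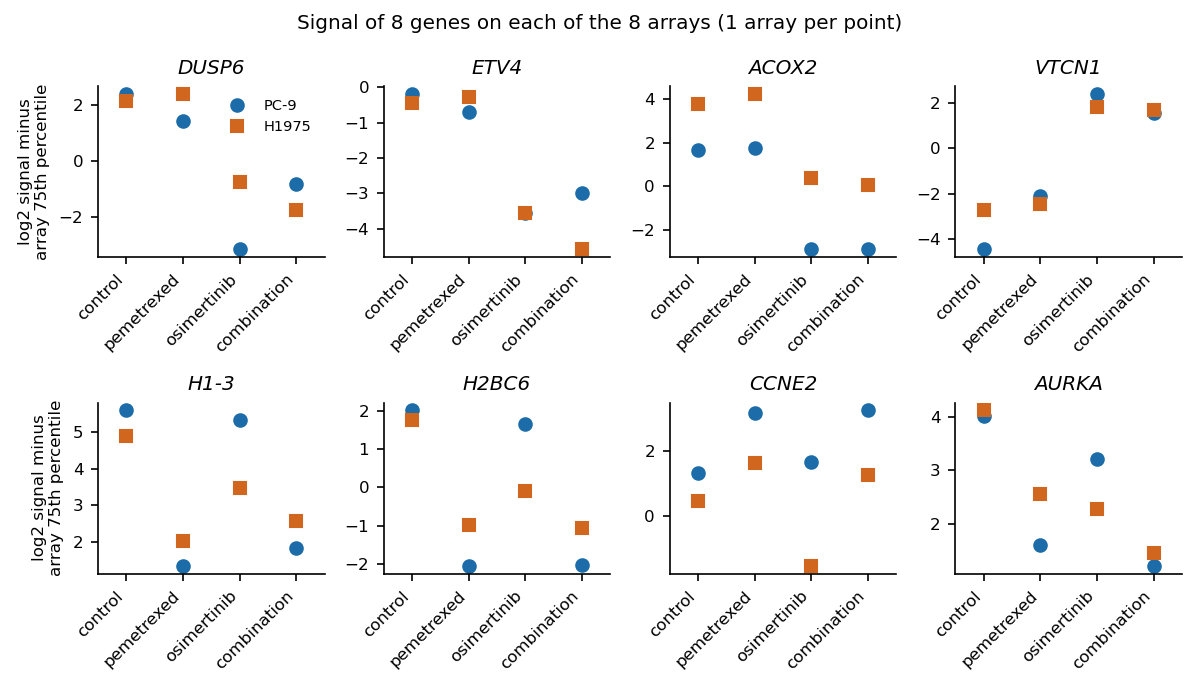
Log2 signal relative to the 75th percentile of the array (vertical axis) under each treatment (horizontal axis) for 8 named genes, with circles for PC-9, squares for H1975 and 1 array per point. DUSP6 stood at 2.40 and 2.15 in the PC-9 and H1975 controls and at -3.14 and -0.74 with osimertinib, and the histone gene H1-3 stood at 5.59 and 4.89 in the controls and at 1.34 and 2.03 with pemetrexed.

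Pemetrexed alone was compared with control to ask what the antifolate did at the same time point. The 8 lowest named genes were all histone genes. The linker histone H1-3 (chromosome 6, 26234699 to 26234758) differed by -4.25 in PC-9 and -2.86 in H1975 (mean -3.56, SE 0.68), H2BC6 (chromosome 6, 26184399 to 26184458) by -4.06 and -2.73 and H2BC7 by -4.19 and -2.73. H1-5, H2AC16, H2AC13, HIST1H2AI and H4C16 were the others, from -4.35 to -2.27 in PC-9 and from -2.43 to -2.26 in H1975. The list of polyadenylated histone genes fell, with medians of -1.18 and -1.86 (camera adjusted p = 3.36e-11), all 11 measured of 13 being lower in both lines and 7 at least 2-fold lower in both. An estimated correlation gave adjusted p = 0.614.

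Mitotic genes were lower while replication genes were not. The G2/M list fell (-0.97 and -0.74, adjusted p = 1.88e-14), with all 37 genes lower in both lines and 11 at least 2-fold lower in both. PLK1 was at -2.46 and -1.40, AURKA at -2.43 and -1.57, the kinesin KIF20A at -2.13 and -1.69 and MKI67 at -0.77 and -0.88. The G1/S and DNA replication list rose (0.27 and 0.23, adjusted p = 0.000341, 28 of 37 genes higher in both), with the cyclins CCNE2 at 1.85 and 1.17 and CCNE1 at 0.53 and 1.08. With an estimated correlation, adjusted p = 0.614 for G2/M and 0.825 for G1/S. Of the enzymes that pemetrexed inhibits, TYMS was at 0.25 and 0.18 and GART at -0.09 and 0.10, with a GART mean of 0.00 that became -0.14 over all its probes.

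Interferon and amino acid response genes were higher. The interferon response list rose (0.70 and 0.35, adjusted p = 1.61e-12), with 25 of 28 genes higher in both lines, among them the antiviral MX1 (1.65 and 0.80), MX2 (1.54 and 0.81) and OAS1 (0.74 and 0.58). The ATF4 amino acid response rose (0.33 and 0.42, adjusted p = 1.5e-08), with 18 of 24 genes higher in both, such as NUPR1 (4.01 and 1.30), the glutathione-degrading CHAC1 (3.74 and 1.20) and asparagine synthetase ASNS (1.81 and 0.85). For both lists an estimated correlation gave adjusted p = 0.614. p53 targets rose by smaller amounts (0.27 and 0.05, adjusted p = 0.00887), with CDKN1A, the CDK inhibitor p21, at 1.02 and 0.70. The unfolded protein response rose by 0.21 and 0.12 (adjusted p = 0.00774). With an estimated correlation, adjusted p = 0.614 and 0.673. Ribosome biogenesis and MYC targets fell (-0.60 and -0.11, camera adjusted p = 1.97e-05), with 24 of 30 genes lower in both lines. Folate and thymidylate genes rose (0.06 and 0.18, adjusted p = 0.0163, 12 of 25 higher in both). An estimated correlation gave adjusted p = 0.746 and 0.721. The ribosome call was lost without PC-9 pemetrexed, and the folate call without H1975 control or H1975 pemetrexed. Heat shock genes fell (-0.37 and -0.18, adjusted p = 0.0234, and adjusted p = 0.763 with an estimated correlation), with HSPA1A at -0.59 and -0.55. That call was lost without PC-9 pemetrexed (median over both lines -0.09, from -0.26) or H1975 control (-0.28), with the authors' table and without a filter on dim probes, and the median was -0.44 without H1975 pemetrexed and -0.17 with normexp or -0.15 with quantile normalization. Outside the lists, CCDC187 (3.40 and 2.16), CDHR4 (1.80 and 1.97), NEURL3 (3.09 and 1.79) and WNT11 (2.44 in PC-9, at least 1.74-fold in H1975) were among the 8 highest.

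In both lines 134 of 22763 genes were at least 2-fold higher, against 12.8 if unrelated, and 138 at least 2-fold lower, against 11.6, with r = 0.40 across genes. With limma 0 genes passed (smallest adjusted p 0.436, 2548 with an unadjusted p under 0.05), and 0 in the additive fit (smallest adjusted p 0.0883, 5115 unadjusted). Adjusted over the list alone, 9 of 11 histone genes and 12 of 37 G2/M genes passed, and 0 of the interferon list. The G1/S call was lost in the fits without PC-9 control (fitted median -0.04) or H1975 pemetrexed (-0.00). Both lay below the lines' own medians of 0.27 and 0.23, since the missing array was filled in from the other treatments. The p53 and unfolded protein calls were lost without the same arrays (p53 0.08 and 0.25, unfolded protein 0.02 and 0.17). Without PC-9 pemetrexed the G2/M median moved from -0.82 to -0.52, G1/S from 0.24 to 0.44, p53 from 0.17 to 0.07 and unfolded protein from 0.13 to 0.21, without H1975 control G1/S moved to 0.48 and unfolded protein to 0.25, without PC-9 control interferon moved from 0.51 to 0.26, and without H1975 pemetrexed ATF4 from 0.41 to 0.23.

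The combination was compared with control for the joint effect. Genes named for each drug alone were again at the extremes. VTCN1 was higher by 6.05 and 4.42 (mean 5.23, SE 0.59), while ACOX2 (-4.56 and -3.75, SE 0.30), DUSP6 (-3.20 and -3.91, SE 0.80), ETV4 (-2.79 and -4.14, SE 0.49) and NT5E (-3.04 and -3.33) were lower, as with osimertinib. The histone genes H2BC6 (-4.05 and -2.81) and H2BC7 (-3.40 and -2.73) and the helicase PIF1 (-4.46 and -3.19) were lower too, and the acute-phase gene SAA1 was higher (3.39 in PC-9, at least 12.8-fold in H1975). CNN1, a smooth muscle actin-binding protein, was at least 47.2-fold higher in PC-9 and higher by 3.25 in H1975. The panel stood at -1.39 and -0.81 for MYC, 1.68 and 0.67 for CDKN1A and 0.21 and -0.14 for TYMS. The mean of TYMS (0.03) changed sign when arrays were centred on the median (-0.03).

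Of the lists, G2/M fell (medians -1.05 and -1.33, adjusted p = 1.08e-13), with all 37 genes lower in both lines and 20 at least 2-fold lower in both, PLK1 at -2.84 and -2.73 and AURKA at -2.82 and -2.67. Ribosome biogenesis fell (-1.25 and -1.18, adjusted p = 4.5e-17, all 30 genes), with RRS1 at -2.14 and -1.84. MAPK output (-1.34 and -1.74, adjusted p = 4.09e-08, 20 of 22), heat shock (-0.84 and -0.93, adjusted p = 1.97e-05, 13 of 15), purine and pyrimidine synthesis (-0.50 and -0.67, adjusted p = 1.97e-05, 14 of 16) and histones (-0.71 and -1.17, adjusted p = 0.00688, 8 of 11) fell. Interferon genes rose (0.83 and 0.32, adjusted p = 9.19e-10, 21 of 28, MX2 at 2.94 and 1.74), as did CDK inhibitors and quiescence (0.53 and 0.19, adjusted p = 0.0003, 12 of 21) and lysosome and autophagy (0.21 and 0.27, adjusted p = 0.000924, 13 of 24). Each of these 9 lists had adjusted p = 0.614 with an estimated correlation. Replication genes did not pass (0.13 and -0.20, adjusted p = 0.723), nor did folate and thymidylate (adjusted p = 0.802).

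In both lines 665 of 22659 genes were at least 2-fold higher, against 104 if unrelated, and 445 at least 2-fold lower, against 67.5, with r = 0.53 across genes. With limma 0 genes passed (smallest adjusted p 0.0956, 6292 with an unadjusted p under 0.05). Adjusted over the list alone, 29 genes of each of the G2/M and ribosome lists, 12 MAPK, 8 purine and 7 histone genes passed. Normexp moved the MAPK median over both lines from -1.51 to -0.90 and the purine median from -0.57 to -0.35, the same as quantile normalization. Quantile normalization moved the lysosome median from 0.19 to 0.41, the mean of probes to 0.29, the authors' table to 0.28 and centring on the median to 0.13, and the CDK inhibitor median went from 0.25 to 0.41 without the H1975 combination array.

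**Figure D2:**
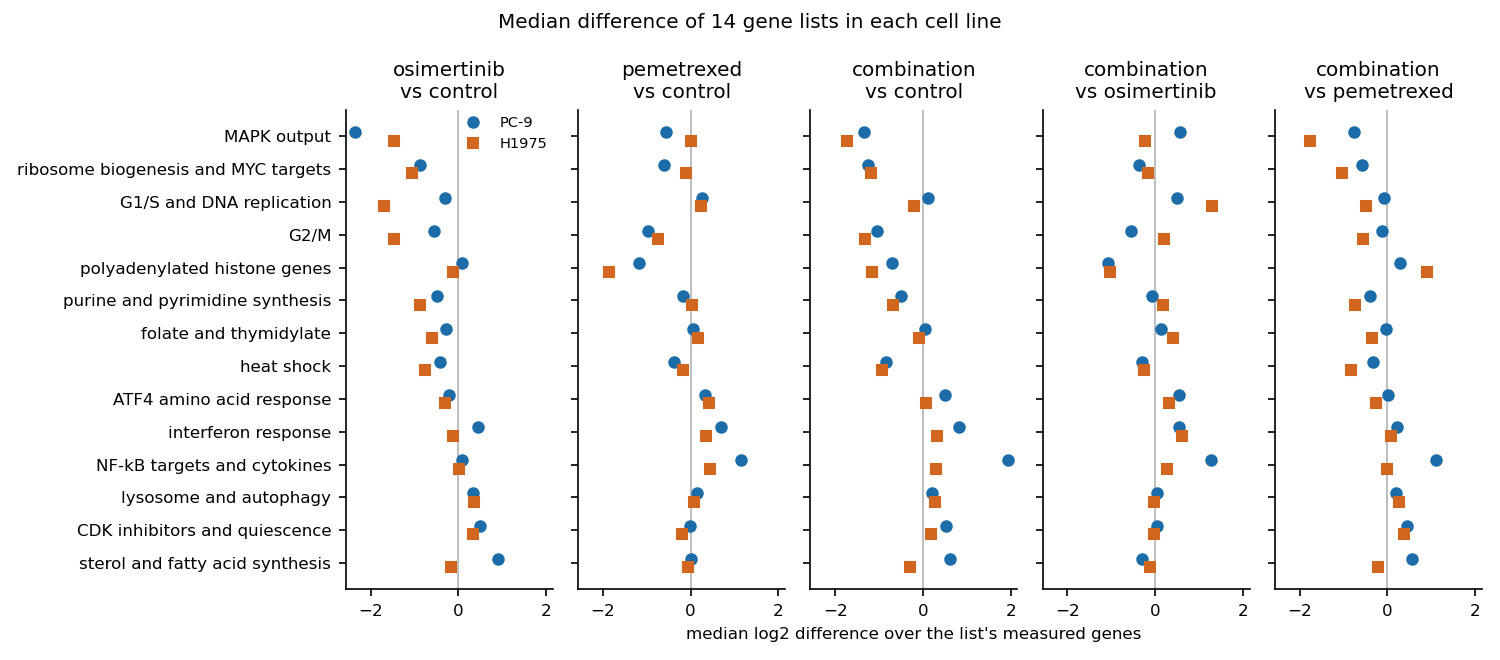
Median log2 difference (horizontal axis) of 14 gene lists in 5 comparisons (panels), with 1 point per line, PC-9 as circles and H1975 as squares. MAPK output was below 0 in each comparison of arrays with osimertinib to arrays without it (-2.35 and -1.47 against control), and histones were below 0 in each comparison of arrays with pemetrexed to those without it (-1.18 and -1.86 against control).

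**Figure D3:**
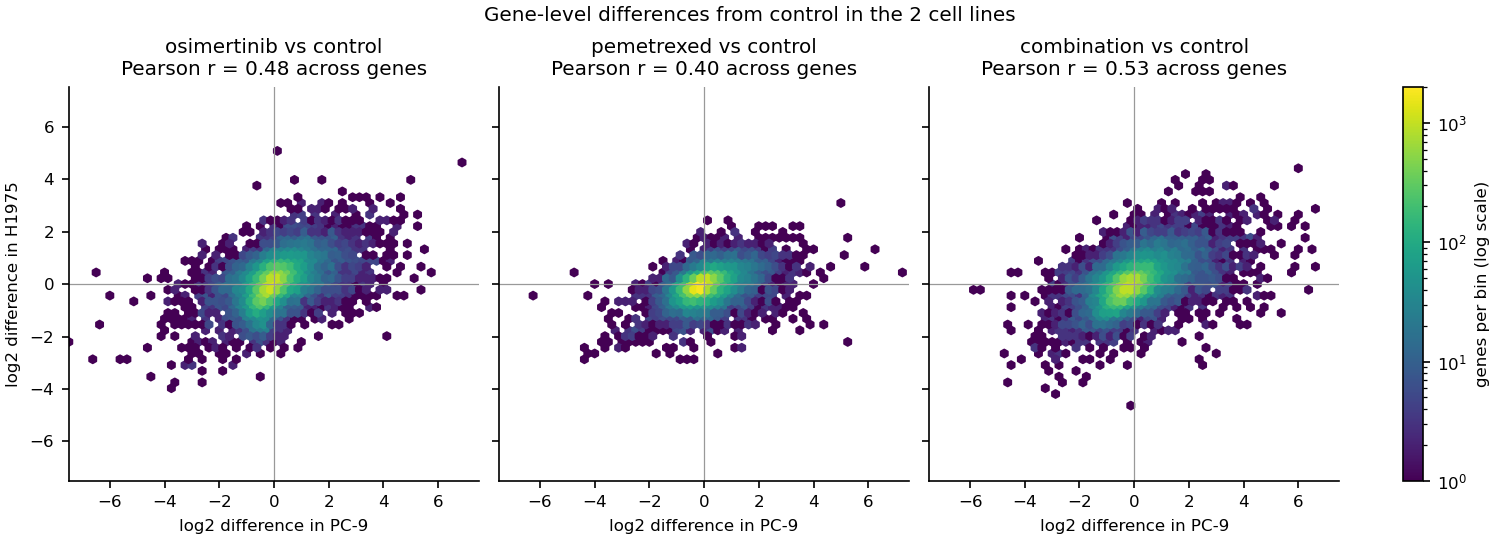
Each gene's log2 difference from control in PC-9 (horizontal axis) and in H1975 (vertical axis) for osimertinib, pemetrexed and the combination, with colour for the number of genes per bin on a log scale. The cloud tilts upward in all panels (r = 0.48, 0.40 and 0.53 across genes).

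The combination was compared with osimertinib alone because the series asks how pemetrexed altered expression under osimertinib. Replication genes were higher when pemetrexed was present. The G1/S and DNA replication list rose by a median of 0.50 in PC-9 and 1.28 in H1975 (adjusted p = 9.25e-22), 32 of 37 genes being higher in both lines, with CCNE2 at 1.58 and 2.77 (mean 2.18, SE 0.55), the licensing factor CDT1 at 1.15 and 2.48 and CCNE1 at 1.30 and 1.14. DNA repair rose (0.28 and 1.22, adjusted p = 1.7e-09, 17 of 24, RAD51AP1 at 0.74 and 2.00), as did folate and thymidylate (0.13 and 0.40, adjusted p = 6.68e-06, 16 of 25), where TYMS was at 0.61 and 1.57 and the ribonucleotide reductase subunit RRM2 at 1.19 and 1.90. Adjusted p = 0.614 with an estimated correlation for these 3 lists.

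Beside osimertinib, histone, interferon and ATF4 genes moved in the same direction as with pemetrexed alone. Histones fell (-1.08 and -1.02, adjusted p = 2.82e-08, all 11 genes lower in both). Interferon genes rose (0.54 and 0.61, adjusted p = 5.67e-13, 24 of 28, HERC5 at 1.12 and 1.07), and so did the ATF4 response (0.55 and 0.31, adjusted p = 5.35e-10, 17 of 24, CHAC1 at 4.25 and 1.41, ASNS at 2.33 and 0.91). Adjusted p = 0.614 with an estimated correlation for these 3 lists. The erythroid hormone gene ERFE (chromosome 2, 239074260 to 239074319) was higher by 2.14 and 1.68 (mean 1.91, SE 0.18) and COCH by 1.97 and 1.71. PIF1 (chromosome 15, 65107916 to 65107975) was the lowest by the smaller of the lines' differences (-3.84 and -1.90). CDKN1A was at 2.28 and 0.61. In PC-9 the EGFR ligands HBEGF (3.57) and AREG (3.06) and the MAPK output DUSP6 (2.34) were higher than with osimertinib alone, whereas in H1975 they were at 0.71, 0.41 and -1.02; for this contrast a difference between lines was not tested. The G2/M list, lower in both lines with pemetrexed alone, did not pass here (-0.56 and 0.19, adjusted p = 0.108). Ribosome biogenesis genes were called lower (-0.38 and -0.17), but not with an estimated correlation. That call was lost without PC-9 osimertinib or the H1975 combination array.

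In both lines 128 of 22536 genes were at least 2-fold higher, against 16.1 if unrelated, and 64 at least 2-fold lower, against 8.03, with r = 0.38 across genes. With limma 0 genes passed (smallest adjusted p 0.573, 2304 with an unadjusted p under 0.05). Adjusted over the list alone, 9 histone, 5 ATF4 and 1 G1/S genes passed. Without H1975 osimertinib the median over both lines moved from 0.94 to 0.37 for G1/S, from 0.77 to 0.21 for DNA repair and from 0.31 to 0.17 for folate. Without PC-9 osimertinib the first 2 moved to 1.48 and 1.28, and without the PC-9 combination array interferon moved from 0.60 to 0.39.

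The combination was compared with pemetrexed alone for what osimertinib added. ACOX2 (-4.67 and -4.21, mean -4.44, SE 0.30), ETV4 (-2.28 and -4.29), DUSP6 (-2.22 and -4.13), SPRY4 (-2.37 and -3.04) and NT5E (-2.02 and -3.33) were lower, and VTCN1 was higher (3.70 and 4.18, mean 3.94, SE 0.59). SAA1 (2.88 in PC-9, at least 14.7-fold in H1975) and SAA2 (3.41 in PC-9, at least 5.77-fold in H1975) were higher. Ribosome biogenesis fell (-0.58 and -1.03, adjusted p = 3.53e-20, all 30 genes, PPAN at -1.33 and -1.35), as did MAPK output (-0.77 and -1.78, adjusted p = 4.63e-11, 19 of 22), purine and pyrimidine synthesis (-0.40 and -0.74, adjusted p = 1.95e-08, 15 of 16) and heat shock (-0.33 and -0.83, adjusted p = 1.57e-05, 13 of 15). CDK inhibitors and quiescence (0.45 and 0.37, adjusted p = 5.95e-05, 13 of 21, YPEL3 at 1.42 and 1.81), histones (0.28 and 0.91, adjusted p = 0.000239, 9 of 11, HIST1H2AC at 1.53 and 2.67) and lung epithelial lineage (0.21 and 0.41, adjusted p = 0.00364, 13 of 23, HOPX at 2.02 and 2.43) rose. All 7 had adjusted p = 0.614 with an estimated correlation.

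In both lines 217 of 22512 genes were at least 2-fold higher, against 32.1 if unrelated, and 121 at least 2-fold lower, against 18.5, with r = 0.34 across genes. With limma 0 genes passed (smallest adjusted p 0.232, 3407 with an unadjusted p under 0.05), and adjusted over the list alone 29 ribosome, 10 MAPK, 8 purine and 5 heat shock genes passed. Normexp moved the MAPK median over both lines from -1.35 to -0.76 and the lung lineage median from 0.30 to 0.14, which was 0.17 without the H1975 combination array. Without H1975 pemetrexed the heat shock median moved from -0.60 to -0.38 and the histone median from 0.63 to 0.37, which was 0.97 without PC-9 pemetrexed.

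Non-additivity asked whether the combination departed from the sum of the single drugs. Mitotic genes were less low than the sum of the single effects: the G2/M list departed upward by a median of 0.45 in PC-9 and 0.88 in H1975 (adjusted p = 1.17e-13), with 35 of 37 genes above 0 in both lines, TPX2 at 0.70 and 1.59 and CENPA at 0.76 and 1.05. The G1/S list (0.21 and 1.13, adjusted p = 6.6e-12, 33 of 37, CDT1 at 0.61 and 2.15, MCM10 at 0.59 and 1.85), DNA repair (0.15 and 1.16, adjusted p = 7.96e-07, 19 of 24) and histones (0.21 and 0.74, adjusted p = 0.000166, 9 of 11) also departed upward. All 4 had adjusted p = 0.614 with an estimated correlation. PGF, a placental growth factor, was the gene furthest above additivity in both lines (1.94 and 1.27, SE 0.58), and the ubiquitin ligase RNF144B the furthest below (-1.56 and -1.42, SE 0.43).

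With limma 0 genes passed (smallest adjusted p 1, 554 with an unadjusted p under 0.05). Without H1975 osimertinib the G1/S and DNA repair calls were lost (medians over both lines 0.07 and 0.13, adjusted p = 0.258 and 0.372), and the histone call was lost without H1975 pemetrexed (0.18, adjusted p = 0.0617). The G2/M call held without each array, but its median over both lines of 0.65 became 0.16 without H1975 osimertinib, 0.31 without PC-9 pemetrexed and 1.12 without PC-9 osimertinib. G1/S moved from 0.67 to 1.29 without PC-9 osimertinib, 0.40 without PC-9 pemetrexed and 0.41 without H1975 control, DNA repair from 0.63 to 1.15 and 0.40 without the same PC-9 arrays, and histones from 0.50 to 0.33 without PC-9 osimertinib.

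The last comparison asked whether the lines responded differently, from the 2 arrays with a drug against the 2 without it in each line. Of the 10 genes named for each drug, 1 with osimertinib and 2 with pemetrexed were above background on all 8 arrays, so most differences rest in part on background and are given as bounds within a line. FLJ42627, measured on all arrays and named for both drugs, differed through the H1975 pemetrexed array alone. It stood at 6.29 there and at -1.73, -1.11 and -1.33 in H1975 control, osimertinib and combination. With osimertinib, TRAF1, a TNF receptor adaptor, was on average at least 5.95-fold higher in PC-9 and differed by -0.71 in H1975. COL21A1 was at least 6.17-fold higher in H1975 and not above background on any PC-9 array. NTSR1 (at least 15.1-fold lower), DMBT1 (-3.43) and OLR1 (4.18) changed in PC-9 and were not above background on any H1975 array. With pemetrexed, H1-5, measured on all arrays, had effects of -4.21 in PC-9 and -1.47 in H1975 (difference 2.74, SE 0.71, adjusted p = 0.454). LILRA5, an immunoglobulin-like receptor, was at least 7.16-fold higher in PC-9 and not above background on any H1975 array. These genes were taken by size alone, because 0 passed in limma for either drug (smallest adjusted p 0.167 for osimertinib and 0.376 for pemetrexed, with 4753 and 2669 genes at an unadjusted p under 0.05).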

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

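All tests in this part were chosen after the results were seen.

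The list effects of osimertinib differed between the lines for 16 of 30 lists (H1975 minus PC-9, arrays with the drug against arrays without it, camera at the preset correlation). The differences were -0.849 for G1/S and DNA replication (adjusted p = 2.76e-08), -0.679 for G2/M (1.88e-08), -0.538 for DNA damage response and repair (0.00174), -0.522 for hypoxia and glycolysis (7.18e-06), -0.791 for NF-kB targets (0.00103), -0.408 for interferon response (0.000473) and -0.349 for heat shock (0.000473). They were -0.319 for YAP/TEAD targets (0.00994), -0.276 for epithelial genes (0.0014), -0.257 for ribosome biogenesis (0.000332), -0.245 for folate and thymidylate (0.0414), -0.235 for purine and pyrimidine synthesis (0.000721), -0.176 for unfolded protein response (0.0172), -0.152 for ATF4 response (0.0102), -0.150 for p53 targets (0.0295) and -0.847 for sterol and fatty acid synthesis (1.14e-12). Those of pemetrexed differed for 10 of 30 lists: 0.539 for G1/S and DNA replication (0.000332), 0.506 for G2/M (2.35e-05), 0.399 for DNA repair (0.00196), 0.349 for ribosome biogenesis (1.02e-07), 0.346 for folate and thymidylate (0.01), 0.146 for purine synthesis (0.00718), -0.239 for hypoxia (0.0416), -0.258 for p53 targets (0.0202), -0.269 for unfolded protein response (0.00141) and -1.01 for NF-kB targets (4.05e-07, effects 1.26 in PC-9 and 0.42 in H1975). With an estimated correlation 0 of these 26 differences passed (adjusted p = 0.695 for each, and 0.714 for G1/S with pemetrexed). The 16 differences with osimertinib were all below 0, while the median over all genes was 0.069. Whether a shift common to these lists underlies them was not tested. Pemetrexed alone gave similar G1/S (0.268 in PC-9, 0.232 in H1975) and DNA repair medians (0.123, 0.0631). Beside osimertinib they were 0.501 and 1.285, and 0.282 and 1.225, so these gaps rest on the H1975 osimertinib and combination arrays. The NF-kB gap with osimertinib was seen beside pemetrexed (1.0997, -0.00278) and not with osimertinib alone (0.0823, 0.00638). That with pemetrexed was seen alone (1.1499, 0.444) and beside osimertinib (1.28, 0.263). Each line was on its own slide, scan and software version, which cannot be told apart from the line.

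The histone list was lower with pemetrexed in both lines. Scaling of whole arrays is argued against, since the highest median over 4 other scalings of the 4 pairs with and without pemetrexed was -0.828, and so is 1 deviant array, since the highest of the medians of these pairs, which share no array, was -1.02. The G1/S list did not fall with the histones in the same pairs (lowest median 0.232), which goes against fewer cells expressing replication genes. That is limited: against control the rise had adjusted p = 0.825 by camera with an estimated correlation. In the fits without PC-9 control or without H1975 pemetrexed the G1/S median was -0.045 or -0.003. Such a fit fills in the missing array from the line difference under the other treatments. These values are therefore not differences within a line. For fewer dividing cells the values went both ways: against control, G2/M genes (-0.97 in PC-9 and -0.74 in H1975) and MKI67 (-0.77 and -0.88) were lower, but beside osimertinib they were lower in PC-9 (-0.56 and -0.26) and higher in H1975 (0.19 and 0.34). Cell division and DNA synthesis were not measured and stay open.

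In H1975 the replication list was lower with osimertinib alone than with the combination (combination minus osimertinib 1.28), and its non-additivity was 1.13. Swapped labels of those arrays are argued against, since histones were lower in the array labelled combination (-1.02). Scaling as the cause of the non-additivity is argued against too (lowest median non-additivity over other scalings 0.983). A deviant H1975 osimertinib array stays open: the same list had a non-additivity of 0.213 in PC-9, the same direction but smaller, and only 1 array decides. No biological explanation was tested.

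The sterol and fatty acid synthesis list was higher with osimertinib in PC-9 (effect 0.77) and not in H1975 (-0.22). A single deviant PC-9 array is argued against, since the lower of the PC-9 medians from pairs that share no array was 0.565. Uniform compression of signal on the H1975 slide is argued against as the whole cause: it would need a factor of 0.0519 or less, but 7 lists lowered in both osimertinib comparisons responded at least 0.626 times as much as in PC-9. These lists were chosen as lower in both lines, so a list lower in PC-9 alone could not enter, and raised lists were left out. Raised lists went both ways with osimertinib alone: lysosome genes were at 0.32 in PC-9 and 0.35 in H1975, YAP/TEAD targets at 0.77 and 0.04. Slide, scan and software (difference -0.847) cannot be told apart from the line, because no slide held both lines. A biological difference between the lines remains possible and was not tested apart from them.

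With osimertinib present against absent, in a fit with the line as a term, the real split gave 1369 genes and the highest of the other splits with 2 arrays of each line on each side gave 0. That fit has no term for the drugs, so in the other splits an osimertinib effect falls at least in part into the error. Their 0 genes are therefore no measure of chance. With pemetrexed the real split gave 0 genes and the highest other 1369, in the split by osimertinib, which is a structure of the arrays. As many genes as in the real split came from 1 of 18 such splits for osimertinib, and 18 splits are too few for a share under 0.05. For pemetrexed it was 18 of 18, which says nothing, because every split reaches the 0 genes of the real one.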

How the results depend on the processing

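The additive fit and the lists without each array were added after the data were seen; all other alternatives were planned. Of the counts of genes past the threshold, 131 kept their value of 0 and 10 rose above it. For osimertinib they were 52 with normexp (44 up, 8 down), 160 with the filter on all 8 arrays (115 up, 45 down), 754 with a variance trend (402 up, 352 down) and 2449 in the additive fit. For the combination against control they were 1132 with normexp (512 up, 620 down), 1798 with the filter (735 up, 1063 down) and 2405 with the trend (943 up, 1462 down). The trend gave 1 for the combination against pemetrexed. The difference between lines with osimertinib gave 664 with normexp (388 up, 276 down) and 75 with the trend (32 up, 43 down). The filter left 20042 genes. The cause of these differences was not tested. All counts without 1 array were 0. With 1 array left out, the lone array of a treatment is assumed to vary like the others.

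Of the values of single genes, 3754 were on the same side, 220 passed where the planned fit had not, and 23 reversed. Over the mean of all detected probes, those that reversed were MYC (0.36), GART (-0.14) and BCL2L11 (-0.0751) with pemetrexed. MKI67 (-0.0539), TGFA (0.19) and XRCC3 (0.38) did in the combination against osimertinib, EGFR against pemetrexed (0.0249) and TMPRSS6 (-0.21) and ETV1 (0.31) in non-additivity. With normexp and with quantile normalization, HSP90B1 with pemetrexed was 0.0141 and 0.00917, and in the combination PSAT1 was 0.0026 and 0.0631 and ABCA3 0.00266 and 0.0146. CCND1 non-additivity was -0.0326, -0.0103 and, in the authors' table, -0.0165, and ETV1 0.14 with normexp. TYMS in the combination was -0.0296 when centred on the median. SPRY4, read from another probe under the filter, was 0.042 with osimertinib, -0.10 against osimertinib and -0.29 in non-additivity. The cause was not tested.

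Of 73 list calls, 36 held without each array, 58 held under the other settings with the preset correlation, 36 held under all of these, and 0 held with an estimated correlation. Over all settings, 5 reversed in direction by camera, the values below being medians. Without 1 array at a time, the sterol list with osimertinib (0.39) ran from 0.0166 (without PC-9 osimertinib) to 0.75. For the combination against pemetrexed, G1/S (-0.29) ran from -0.61 to -0.0358 and G2/M (-0.29) from -0.64 to 0.0165, both calls being lost without H1975 pemetrexed. MAPK non-additivity (0.55) ran from 0.0772 to 0.76, and it reversed without PC-9 pemetrexed (0.20) or the PC-9 combination array (0.0888). The cause was not tested.

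The median difference over all genes lay beyond 0.1 in a few cases: at -0.145 for the combination against control when centred on the median, and without a filter on dim probes at -0.135 for pemetrexed and 0.114 for the combination against pemetrexed. Signal over background limits genes that were dim on 1 array, whose sizes are lower bounds. Slide as a block was not run, because slide and cell line coincide.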

Other observations

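Among other lists with osimertinib against control, EGFR family and ligands had medians of -0.33 in PC-9 and -0.37 in H1975 (camera adjusted p = 0.488), with AREG at -2.48 and -2.44, ERBB2 at 0.79 and 1.08 and ERBB3 at 0.86 and 0.60. The BCL2 family stood at 0.04 and -0.03 (adjusted p = 0.989), with BMF at 3.98 and 2.06 (2.64 in the additive fit, SE 0.43, adjusted p = 0.0295), BCL2L1 at -1.38 and -0.97 and BCL2 at -1.09 and -1.13. Bypass receptors and ligands stood at 0.31 and 0.06 (adjusted p = 0.31), with IGFBP5 at least 14.7-fold and 3.67-fold higher and FGFR3 at 0.88 and 1.15. Mesenchymal genes stood at 0.26 and 0.30 (adjusted p = 0.309) and epithelial genes at 0.19 and -0.07 (adjusted p = 0.245), with MUC1 at 2.27 and 1.31. YAP/TEAD targets were at 0.77 and 0.04 (adjusted p = 0.02, with the call lost without PC-9 control or PC-9 osimertinib). Their median over both lines was 0.38, and 0.23 without either of these arrays, 0.65 without H1975 control and 0.59 without H1975 osimertinib. Hypoxia and glycolysis were at -0.05 and -0.58 (adjusted p = 0.0186, lost without H1975 control, -0.11, or H1975 osimertinib, -0.28, and with 4 of the alternatives, among them quantile normalization), with HK2 at -1.80 and -0.92 and VEGFA at -1.75 and -0.83. Sterol and fatty acid synthesis were at 0.91 and -0.18 (adjusted p = 0.0354, lost without PC-9 control or PC-9 osimertinib, where the median over both lines fell from 0.39 to 0.07 and 0.0166, and without H1975 pemetrexed or with the filter on all 8 arrays, where it was 0.39 and 0.34). It was 0.75 without H1975 control and 0.73 without H1975 osimertinib. With an estimated correlation, adjusted p = 0.614 for YAP/TEAD targets, 0.763 for hypoxia and 0.876 for sterol synthesis.

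Markers of other cell types were measured in part. Fibroblast markers stood at 0.56 and 0.90 with osimertinib (adjusted p = 0.0475, 4 of 10 measured, adjusted p = 0.614 with an estimated correlation, lost without any 1 array other than PC-9 control or PC-9 osimertinib and with 5 alternatives). Their median over both lines, 0.80, was 0.49 without H1975 osimertinib, 0.19 without a filter on dim probes and 0.37 with normexp, and at least 0.67 in the other losses. With osimertinib, leukocyte markers stood at 0.48 and 0.21 (adjusted p = 0.0647, 11 of 13), endothelial at -0.68 and 0.05 (adjusted p = 0.546, 5 of 8), erythroid at -0.16 and 0.06 (adjusted p = 0.859, 4 of 6) and neuroendocrine at 0.01 and -0.23 (adjusted p = 0.57, 4 of 10). With pemetrexed, NF-kB targets and cytokines stood at 1.15 and 0.44 (adjusted p = 0.000239, and 0.614 with an estimated correlation), with IL1B at 2.03 and 0.93. The call was lost in the fit without PC-9 control, where the fitted median was -0.02, against 0.78 over both lines with all arrays. That fit fills in PC-9 control from the line difference under the other treatments, and its median lay below both lines' own values. The median was 0.22 with normexp and 1.40 in the fit without H1975 control. The p53 target TP53INP1 was at least 10.9-fold higher in PC-9 and higher by 2.60 in H1975 with osimertinib. Between pairs of arrays that share none, r across 20009 genes, which are not independent replicates, between the effect of a drug given alone and beside the other drug was 0.68 in PC-9 and 0.82 in H1975 for osimertinib, and 0.58 and 0.50 for pemetrexed.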
